A study of Mus musculus with 6 samples.

How the data were processed

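Newborn back skin was dissociated, and interfollicular epidermal cells positive for EpCAM and Sca1 with high α6-integrin were sorted, per the labels. Total RNA was amplified before library construction and sequenced as single reads. The deposited files hold raw counts per gene symbol, 1 file per library and 24453 symbols in each, with no normalization by the authors. The submitters' processing notes name TopHat2 2.0.13, Cufflinks 2.2.1, HTSeq 0.6.1, DESeq2 1.6.3 and the build mm10, with no role for each. The annotation, the strand setting of the counting and any filter are not given in the sources used here, so genes that overlap on either strand have uncertain counts. The values were checked to be whole numbers with a different total in each library. Of the symbols, 4791 had no count in any library.

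There were 3 control and 3 Eed cKO libraries. Totals ran from 25481306 to 29998531 counts in control and from 20998149 to 27447679 in Eed cKO. Replicate numbers are not stated to pair animals, so the model held genotype alone.

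Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr on the group, which left 14700 and removed 9753. Libraries were scaled by TMM, and a quasi-likelihood F-test was made for each gene with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05. The biological coefficient of variation was 0.334. Log2 fold changes are Eed cKO over control, fitted with edgeR's shrinkage toward 0 by its prior count, and CPM values are TMM-normalised with their SD over 3 libraries. For a gene with no control count the fold is a lower bound against 3 counts over the control group (0.0359 CPM), with counts pooled within a group. For 1 to 3 control counts it is a ratio with an exact 95% interval. Intervals and floors cover counting error only, since reads from amplified RNA are not independent molecules. The smallest two-sided exact permutation p for 3 against 3 libraries is 0.1.

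A set of 24 gene lists with 609 entries was tested with camera from limma 3.58.1 on log2 CPM with prior count 2 and a preset correlation of 0.01, with Benjamini-Hochberg adjustment over the 22 lists with at least 3 tested members. Camera with an estimated correlation and fry were alternatives. Preset camera passed 9 lists, an estimated correlation 1, and fry 8. The lists hold developmental regulators, epidermal compartments, cell cycle genes, imprinted and germline genes, genes of other skin cell types, immediate early genes, genes of the sort and sex-linked genes.

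Genes were named by a rule. It took Eed, Ezh2, Ezh1 and Suz12, then the 10 largest rises and 10 largest falls among called genes with ranges apart and at least 5 CPM in the higher group, leaving out predicted, microRNA and small nucleolar genes. It added up to 4 members of each list with the smallest p-values and a set of marker genes whatever their value (Cdkn2a, Cdkn2b, Sox2, Isl1, Atoh1, Krt8, Krt18, Krt20, Krt5, Krt14, Krt1, Krt10, Lor, Mki67, Trp63, Epcam, Ly6a and Itga6). Some genes that the rule picked are not reported here, which left 116 genes, of which 114 were tested. Genes named outside it were not followed singly under the alternatives, except Hoxa2, Hoxa4 and Hoxc4. The groups, the test, the lists, the rule and the first set of alternatives were chosen before the data were examined.

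The alternatives were RLE and upper-quartile scaling, no filter on low counts (at least 1 count in all), a filter of at least 1 CPM in 3 libraries, DESeq2 1.42.0, limma-voom, robust dispersion, thinning to the smallest library, a replicate block, and leaving out each library in turn. Leaving out Rn45s, and leaving out both libraries numbered 1, were added after seeing the data. List tests used camera and so had no DESeq2, limma-voom or robust value.

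Coordinates are from GENCODE M21 on GRCm38, the assembly that mm10 names. Of the 24453 symbols 24086 matched, 23797 by the current symbol and 289 by a single older one, and 367 did not. Shared exonic bases were counted on either strand. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.

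The pipeline was tested on simulated data of the same size in 5 draws, each with 200 changed genes of about 14417 tested, 50 at each fold. It called 6.80% of genes changed 1.5-fold, 44.0% at 2-fold, 74.4% at 4-fold and 86.0% at 8-fold, and 8.01% of its calls were unchanged genes. A doubled list was called in 5 of 5 draws, and over all draws 1 other list was called. Genes were drawn independently of each other, whereas the estimated correlation in the real data reached 0.71 in the immune list. The simulation therefore does not measure how often correlated lists are called falsely. The neighbour test gave a permutation p of 0.10 for 500 scattered genes and 0.0010 with 20 planted pairs.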

Results

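RNA was sequenced from sorted interfollicular epidermal cells of newborn mouse back skin at postnatal day 0, from Eed conditional knockout (cKO) and control mice. Eed encodes a core subunit of Polycomb repressive complex 2 (PRC2), which methylates histone H3 at lysine 27. There were 3 control and 3 Eed cKO libraries. Total counts were 27324708, 29998531 and 25481306 in control libraries 1, 2 and 3, and 27447679, 25231541 and 20998149 in Eed cKO libraries 1, 2 and 3. Between 16168 and 17289 genes had a count in each library. The labels do not say that the libraries come from separate animals, so each p-value measures only the spread between libraries. That spread may be technical in part or, in control, wholly. The Eed cKO libraries hold more than 1 animal, since Xist was at 8.55 CPM in Eed cKO 2 but at 5430 and 6887 CPM in Eed cKO 1 and 3. The comparison asks which transcripts change in epidermal progenitors when Eed is deleted.

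Eed itself (chromosome 7, 89954654 to 89980983, GRCm38) had counts-per-million (CPM) values of 45.1, 41.1 and 53.1 in control libraries 1, 2 and 3, and of 37.0, 33.7 and 29.2 in Eed cKO libraries 1, 2 and 3. The means were 46.4 ± 6.11 and 33.3 ± 3.90 CPM (SD, n = 3 each), and the log2 fold change was -0.48 ± 0.19 (SE; edgeR adjusted p 0.252), which was not called. The deleted exons are not given in the sources used here, so a whole-gene count checks the deletion little. Eed also shares 261 exonic bases with a gene on the opposite strand. Among the other core PRC2 genes, Ezh2, which encodes the methyltransferase, went from 183 ± 49.5 to 114 ± 27.0 CPM (log2 fold change -0.69, edgeR adjusted p 0.120). Ezh2 was not called with all libraries but was without control 1 (edgeR adjusted p 0.0269). Ezh1 (log2 fold change -0.05) and Suz12 (log2 fold change -0.25) were not called either.

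Of the 11 PRC2 subunit genes tested, 0 rose, 1 fell and 10 did not pass; adjusted over the list alone, 1 rose and 2 fell. The gene that fell was Phf19, an accessory subunit, from 24.2 ± 5.68 to 9.51 ± 2.08 CPM (log2 fold change -1.34, edgeR adjusted p 0.0110). The Phf19 call was lost without control 3 or without Eed cKO 3 (edgeR adjusted p up to 0.0814). Of 21 PRC1 subunit genes, 1 rose, 0 fell and 20 did not pass, and adjusted over the list alone the counts were also 1 and 0. Bmi1, a PRC1 component, rose from 65.4 ± 11.9 to 125 ± 26.0 CPM (log2 fold change 0.94, edgeR adjusted p 0.0154), a call lost without control 1, control 3 or Eed cKO 3 (edgeR adjusted p up to 0.0984). As sets, neither the PRC2 list (camera adjusted p 0.456, and 0.704 with an estimated correlation) nor the PRC1 list (0.406 and 0.519) passed.

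Across the 14700 genes tested with edgeR's quasi-likelihood test and Benjamini-Hochberg adjustment, 499 were higher and 120 lower in Eed cKO at an adjusted p under 0.05. Higher genes made up 80.6% of the 619 calls. At least 2-fold changes were seen in 437 higher and 42 lower genes, and 2185 genes had an unadjusted p under 0.05. In all 619 called genes the ranges of the groups were apart; chance gives this for 10% of genes, but calls made on the same libraries favour it. The higher genes were mostly weakly expressed in control, at a median of 5.59 CPM against 75.8 CPM for the lower genes. Of the higher genes 141 (28.3%) had a control mean under 1 CPM, against 10.5% of all tested genes, and 34 had no control count. Of the lower genes 0 had a control mean under 1 CPM, since a gene near 0 in control can rise but hardly fall. Part of the contrast in control level is therefore built in. The higher count fell to 323 without control 3 and to 302 without Eed cKO 3. The lower count fell to 59 without control 2, 35 without control 3, 51 without Eed cKO 2 and 44 without Eed cKO 3. The higher genes of at least 2-fold numbered 289 without Eed cKO 3, and the lower ones 27 without control 3 and 85 without Eed cKO 1. DESeq2 called 811 higher and 273 lower genes, and edgeR without a filter on low counts 737 and 257.

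**Figure D1:**
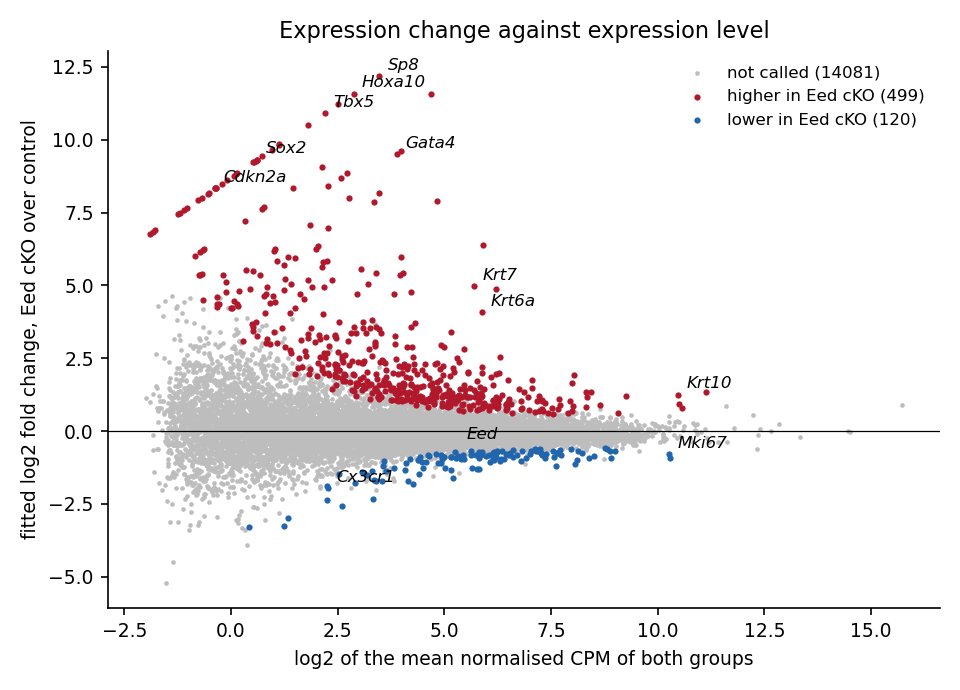
Fitted log2 fold change (Eed cKO over control) against the log2 of the mean normalised CPM, 1 point per tested gene, with 499 higher genes in red and 120 lower genes in blue. The fitted values of genes with no control count depend on the prior count and lie along the upper left edge.

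The strongest rises were in developmental transcription factors that were silent or nearly so in control epidermis. Sp8 (chromosome 12, 118846329 to 118852576), a zinc-finger factor of limb outgrowth, had no count in any control library and 22.3 ± 4.24 CPM in Eed cKO, at least 610-fold higher. The other genes with no control count among the top 10 were Hoxa10 (14.6 ± 6.48 CPM, at least 417-fold higher; chromosome 6, 52231197 to 52240854), Sp9 (11.3 ± 5.91 CPM, at least 327-fold), the limb and heart factor Tbx5 (9.22 ± 2.65 CPM, at least 258-fold) and Dmrt3 (6.94 ± 4.28 CPM, at least 205-fold). The floor behind each bound is 3 counts over the control group, and bounds and ratios use counts pooled within a group, not the means shown. Sim2, a neural and craniofacial factor, had 3 control counts and 31.7 ± 7.64 CPM in Eed cKO, a ratio of 896 (95% counting interval 306 to 4348). The ratio was 835 (285 to 4050) for the endoderm and heart factor Gata4, 542 (150 to 4480) for Hoxd13, and 510 (141 to 4215) for the kidney factor Six2. Each of these calls held in all 6 fits that leave out 1 library, but some folds moved. All control counts of Sim2 and Six2 lie in control 1, without which their log2 fold changes went from 9.60 to 12.68 and from 8.69 to 11.27. For Gata4 it went from 9.50 to 10.36 without control 1 and to 8.90 without control 2. Sp9 shares 270 exonic bases with an overlapping gene.

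The largest falls were smaller. Anks6, a ciliary protein gene, fell from 10.3 ± 5.41 to 1.72 ± 0.332 CPM (log2 fold change -2.58, edgeR adjusted p 0.00686; 0.0660 in limma-voom). Fam189a2 fell from 16.8 ± 0.472 to 3.31 ± 1.31 CPM, and Tgm5, an epidermal transglutaminase, from 27.3 ± 10.1 to 8.29 ± 0.791 CPM. Hoxa3 fell from 30.0 ± 4.81 to 8.45 ± 3.82 CPM. These 4 genes were called in every fit that leaves out 1 library. The inner root sheath keratin Krt71 (log2 fold change -2.36), Enkd1 (-1.88) and the helicase gene Recql4 (-1.80) were each lost in several such fits. Krt71 was lost without control 2, control 3, Eed cKO 2 or Eed cKO 3 (edgeR adjusted p up to 0.284), and Enkd1 and Recql4 without any control or without Eed cKO 2 or 3 (edgeR adjusted p up to 0.0927 and 0.177). The log2 fold change was -1.75 for Krt71 without control 3 and -2.46 for Recql4 without Eed cKO 1. The same held for the myeloid genes Cx3cr1 (log2 fold change -1.95), F13a1 (-1.70) and Cysltr1 (-1.68). Cx3cr1 was lost without any control or Eed cKO 1 or 3 (edgeR adjusted p up to 0.0988), F13a1 without control 1 or 3 or any Eed cKO library (up to 0.297), and Cysltr1 without control 1, control 2 or Eed cKO 2 (up to 0.104).

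**Figure D2:**
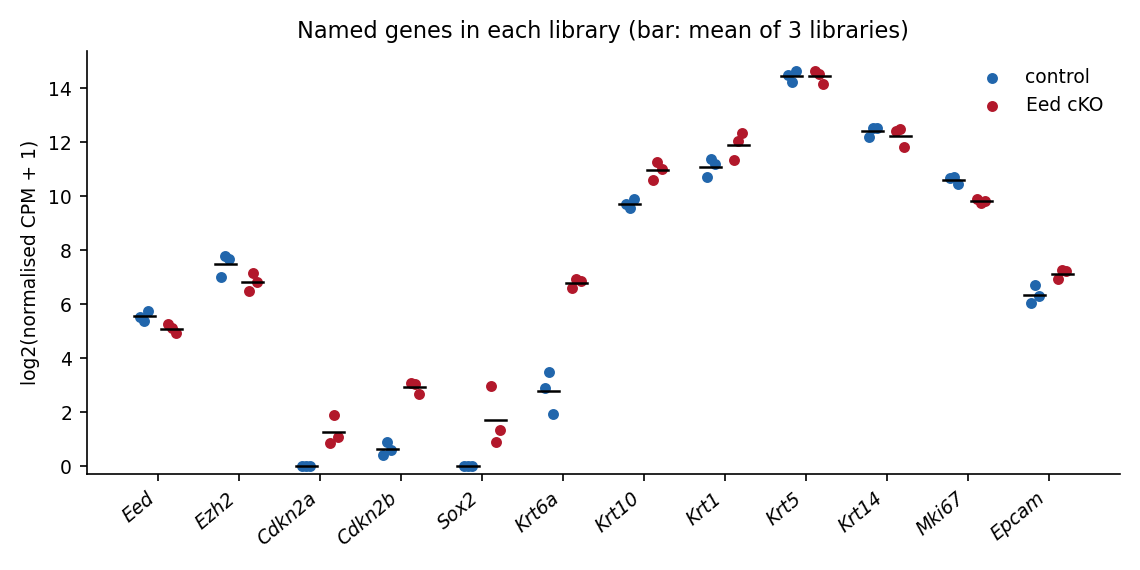
Log2 of normalised CPM plus 1 in each library for 12 genes named in the text, controls in blue and Eed cKO in red, with bars at the mean of 3 libraries. Cdkn2a and Sox2 had no count in any control library, and the Krt5 values of both groups overlap.

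Hox genes encode homeodomain factors of axial identity in 4 clusters. Of the 36 tested, 15 rose, 4 fell and 17 did not pass; adjusted over the list alone, 17 rose and 9 fell. The direction went with the paralog group, but also with the control level. In groups 1 to 8, genes under 5 CPM in control also had positive log2 fold changes. These were Hoxb1 (0.436 CPM in control, log2 fold change 0.41), Hoxd3 (0.294, 2.76), Hoxd4 (0.671, 1.54), Hoxb8 (3.98, 0.65) and Hoxd8 (4.54, 2.88). Among genes at 5 CPM or more only Hoxc8 (26.1, 0.70) was positive. Direction alone does not tell paralog group from control level. All 14 tested genes of groups 9 to 13 rose, among them Hoxd9 from 0.493 ± 0.0403 to 31.2 ± 6.30 CPM, Hoxd11 from 0.0866 ± 0.0593 to 20.5 ± 6.19 CPM and Hoxc10 from 0.0473 ± 0.0416 to 13.5 ± 4.70 CPM. For Hoxd11 the log2 fold change went from 7.84 to 8.47 without control 1. Of the 22 tested genes of groups 1 to 8, 1 rose (Hoxd8, from 4.54 to 33.4 CPM) and 4 fell, and 16 had a negative log2 fold change. The 4 were Hoxa2 (55.5 to 18.4 CPM), Hoxa3 (30.0 to 8.45 CPM), Hoxa4 (13.6 to 4.75 CPM) and Hoxc4 (50.7 to 20.3 CPM). Hoxb1, Hoxb8, Hoxc8, Hoxd3, Hoxd4, Hoxd8, Hoxa2, Hoxa4 and Hoxc4 were chosen after their values were seen. All 4 falls were also called with RLE and upper-quartile scaling, but Hoxa4 was lost without control 2 (edgeR adjusted p 0.1001), Eed cKO 2 (0.0830) or Eed cKO 3 (0.0579). The list moved up in camera (adjusted p 0.000129) but not with an estimated correlation (adjusted p 0.164). Counts of Hoxa2, Hoxa3, Hoxa4, Hoxd11 and Hoxc10 include bases shared with overlapping transcripts, so their values are less certain.

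**Figure D3:**
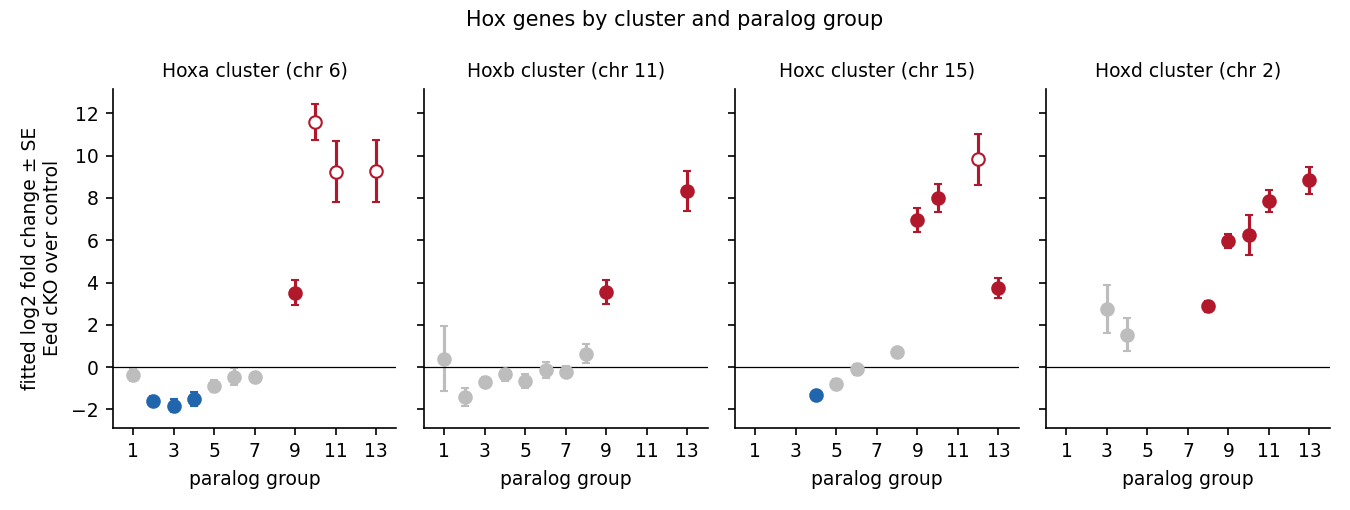
Fitted log2 fold change ± SE (n = 3 libraries each) of the 36 tested Hox genes against paralog group, with a panel per cluster, calls in red (higher) and blue (lower), and genes not called in grey. Hollow points had no control count, and their fitted values depend on the prior count.

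Among 47 tested transcription factor genes of non-epidermal development, 29 rose, 1 fell and 17 did not pass; adjusted over the list alone, 37 rose and 1 fell. Zic1, a neural plate factor, rose from 0.234 ± 0.161 to 56.3 ± 5.70 CPM (edgeR adjusted p 2.84e-08), and the endodermal factor Gata6 from 0.0657 ± 0.0836 to 22.0 ± 7.55 CPM. Their log2 fold changes went from 7.91 to 8.59 without control 1 and from 8.19 to 9.85 without control 2. The gene that fell, Irx2 (229 to 144 CPM), was chosen after its value was seen. The median log2 fold change was 4.50, or 4.43 with genes lacking control counts set at their bound. The list passed in camera (adjusted p 2.02e-37) and, as the only list, with an estimated correlation (adjusted p 0.00208). Only 47 of its 102 genes were tested, however. The filter keeps silent genes mainly where Eed cKO expresses them, so part of this upward shift is built in. This also bears on other lists with members silent in control.

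Merkel cells are touch receptor cells that arise from epidermal progenitors. Of their 15 tested genes 4 rose, 0 fell and 11 did not pass; adjusted over the list alone, 6 rose and 0 fell. The Merkel lineage factors Sox2 and Isl1 had no control count and reached 3.04 ± 3.22 and 3.04 ± 1.83 CPM, at least 90.9-fold and 89.3-fold higher in counts pooled within each group. Sox2 was at 6.74 CPM in Eed cKO 1, 0.883 CPM in Eed cKO 2 and 1.501 CPM in Eed cKO 3, and its fitted log2 fold change went from 9.32 to 7.95 without Eed cKO 1. The adhesion gene Ncam1 rose from 13.01 ± 9.10 to 49.4 ± 11.8 CPM (log2 fold change 1.92, and 2.68 without control 2). The vesicle gene Rab3b rose from 0.709 ± 0.123 to 4.54 ± 2.39 CPM, a call lost without any control or without Eed cKO 1 or 3 (edgeR adjusted p up to 0.160). Atoh1, the Merkel cell determinant, had 0 control and 40 Eed cKO counts, at least 15.3-fold higher, too few to be tested. Among Merkel keratins, Krt18 (log2 fold change 2.69, edgeR adjusted p 0.138) and Krt8 (log2 fold change 1.23, edgeR adjusted p 0.711) were not called. Without control 2 the log2 fold changes were 3.77 and 3.55. Krt20 had 2 control and 24 Eed cKO counts, a ratio of 13.74 (95% counting interval 3.41 to 120.0), and was not tested. The list moved up in camera (adjusted p 2.64e-06) but not with an estimated correlation (adjusted p 0.164).

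Some differentiation genes of the upper epidermis rose. Control libraries already held Krt10 at 847 CPM and Krt1 at 2227 CPM. Whether the share of differentiating cells in the sort changed was not tested. Of 30 suprabasal and cornified envelope genes, 6 rose, 0 fell and 24 did not pass; adjusted over the list alone, 13 rose and 1 fell. The spinous keratin Krt10 (chromosome 11, 99385254 to 99389364) rose from 847 ± 96.0 to 2018 ± 441 CPM (log2 fold change 1.25, edgeR adjusted p 0.00126). The envelope precursor Sprr1a rose from 14.7 ± 4.44 to 55.0 ± 27.7 CPM and the filaggrin-like Hrnr from 12.6 ± 3.30 to 37.9 ± 12.5 CPM. Krt2, a late suprabasal keratin, rose from 0.162 ± 0.281 to 9.36 ± 6.61 CPM (edgeR adjusted p 0.00439), but its DESeq2 adjusted p was 0.0524. Its control counts all lie in control 1, and its log2 fold change of 5.84 was 10.93 without control 1, 5.24 without control 2 and 5.16 without Eed cKO 2. Krt1, the partner of Krt10, had a log2 fold change of 0.85 (edgeR adjusted p 0.0711) and Lor, encoding loricrin, one of 0.92 (edgeR adjusted p 0.115), and neither was called. Both were called without Eed cKO 1 (edgeR adjusted p 0.0105 and 0.0489). The list moved up in camera (adjusted p 2.35e-07) but not with an estimated correlation (adjusted p 0.161).

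Of 18 basal keratinocyte genes tested, 1 rose, 0 fell and 17 did not pass; adjusted over the list alone, 1 rose and 1 fell (camera adjusted p 0.613, and 0.809 with an estimated correlation). Krt5 had log2 fold change -0.01, a sign that flips with RLE and upper-quartile scaling, Krt14 had -0.15 and the basal factor Trp63 -0.37 (edgeR adjusted p 0.994, 0.825 and 0.266). Sfn, encoding 14-3-3 sigma, rose from 117 ± 1.80 to 199 ± 34.5 CPM, a call lost without control 2, control 3, Eed cKO 1 or Eed cKO 2 (edgeR adjusted p up to 0.0966). Wnt4 fell from 925 ± 135 to 577 ± 144 CPM without passing (edgeR adjusted p 0.0672), though it passed without Eed cKO 1 (edgeR adjusted p 0.0127).

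Of 14 tested genes that wounding or stress induces in the epidermis, 6 rose, 0 fell and 8 did not pass; adjusted over the list alone, 6 rose and 1 fell. Krt6a rose from 6.53 ± 3.70 to 111 ± 12.9 CPM (log2 fold change 4.08, edgeR adjusted p 1.22e-05), Krt6b from 2.23 ± 1.07 to 18.6 ± 5.05 CPM and Krt16 from 30.3 ± 5.78 to 118 ± 21.3 CPM. Krt6a and Krt6b are near-identical paralogs, so the split of reads between them is uncertain. The serine protease inhibitor gene Serpinb2 rose from 18.7 ± 5.40 to 75.6 ± 13.2 CPM. The list moved up in camera (adjusted p 0.0256), but not without control 3 (0.106), without Eed cKO 1 (0.0574), without both libraries numbered 1 (0.0557) or with an estimated correlation (0.441).

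Of 27 hair follicle and placode genes, 3 rose, 1 fell (Krt71) and 23 did not pass; adjusted over the list alone, 6 rose and 4 fell. Trps1, a zinc-finger repressor active in follicle development, rose from 11.7 ± 5.69 to 66.5 ± 5.59 CPM. Bmp4 rose from 9.09 ± 0.951 to 22.3 ± 5.53 CPM, lost without control 3 or Eed cKO 3 (edgeR adjusted p up to 0.0833), and the stem cell factor Nfatc1 from 49.1 ± 8.75 to 97.3 ± 31.3 CPM. The Nfatc1 call was lost without control 2, control 3, Eed cKO 1 or Eed cKO 3 (edgeR adjusted p up to 0.126), and that of Krt71 without control 2, control 3, Eed cKO 2 or Eed cKO 3 (edgeR adjusted p up to 0.284). The list's median log2 fold change was 0.03 and its mean -0.07, and camera placed it up without passing (adjusted p 0.901, and 0.949 with an estimated correlation).

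Of 29 proliferation genes tested, 1 rose, 5 fell and 23 did not pass, while 28 had a negative log2 fold change (median -0.55); adjusted over the list alone, 1 rose and 13 fell. The proliferation marker Mki67 fell from 1564 ± 147 to 902 ± 41.8 CPM (log2 fold change -0.79, edgeR adjusted p 0.00765). The mitotic kinase gene Aurkb (log2 fold change -0.86), lost without control 3, Eed cKO 2 or Eed cKO 3 (edgeR adjusted p up to 0.0966), also fell. The topoisomerase gene Top2a (log2 fold change -0.92), lost without control 2, control 3, Eed cKO 1 or Eed cKO 3 (edgeR adjusted p up to 0.0906), fell too. Tyms (log2 fold change -0.82) and Mcm6 (-0.65) completed the 5 and were chosen after their values were seen. The cyclin gene Ccnd1 rose instead, from 199 ± 45.2 to 452 ± 43.5 CPM (edgeR adjusted p 0.00180). The list moved down in camera (adjusted p 8.05e-09) but not with an estimated correlation (adjusted p 0.194).

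Of 11 cyclin-dependent kinase inhibitor and senescence genes tested, 2 rose, 0 fell and 9 did not pass; adjusted over the list alone, 2 rose and 1 fell. Cdkn2b rose from 0.569 ± 0.268 to 6.71 ± 1.12 CPM (log2 fold change 3.54, edgeR adjusted p 0.00167). Its neighbour Cdkn2a (chromosome 4, 89274471 to 89294653), which encodes p16 and p19, had no control count and reached 1.53 ± 1.01 CPM, at least 42.8-fold higher (edgeR adjusted p 0.00883). The Cdkn2a call was lost without Eed cKO 2 (edgeR adjusted p 0.0738; log2 fold change 7.67 against 8.33). Cdkn1b (log2 fold change -0.85, edgeR adjusted p 0.105) was not called. The list's median log2 fold change was -0.08 and its mean 0.92, and camera placed it up without passing (adjusted p 0.901, and 0.938 with an estimated correlation).

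Of 30 imprinted genes, which are expressed from 1 parental allele, 6 rose, 1 fell and 23 did not pass; adjusted over the list alone, 9 rose and 1 fell. The noncoding RNAs Meg3 and Rian of the same domain rose from 6.91 ± 2.54 to 54.2 ± 3.79 CPM and from 1.63 ± 0.757 to 19.4 ± 3.29 CPM. Plagl1 rose from 65.6 ± 29.7 to 167 ± 22.9 CPM, and Mest from 18.8 ± 3.83 to 44.3 ± 12.7 CPM, a call lost without control 3 (edgeR adjusted p 0.0550). Ascl2 fell (14.2 to 5.53 CPM) and was chosen after its value was seen. The list moved up in camera (adjusted p 0.00938) but not with an estimated correlation (adjusted p 0.161). Meg3, Rian and Mest share 1499, 623 and 912 exonic bases with overlapping transcripts.

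Of 37 developmental signalling ligand and antagonist genes, 6 rose, 0 fell and 31 did not pass; adjusted over the list alone, 10 rose and 0 fell. The ligand gene Tgfb2 rose from 6.57 ± 1.86 to 32.2 ± 4.25 CPM, Inhbb from 4.002 ± 1.18 to 20.3 ± 3.01 CPM and Bmp3 from 61.6 ± 21.3 to 206 ± 56.0 CPM. Sfrp1, a Wnt antagonist, rose from 28.3 ± 6.03 to 75.1 ± 22.4 CPM. The list moved up in camera (adjusted p 0.000213) but not with an estimated correlation (adjusted p 0.126). Of 7 germline genes 1 rose, Tdrd1, and 0 fell, with the same counts adjusted over the list alone (camera adjusted p 0.967, and 0.978 with an estimated correlation). The Tdrd1 call was lost without any control or without Eed cKO 2 or 3 (edgeR adjusted p up to 0.209), and the germline list passed upward without Eed cKO 1 (camera adjusted p 0.0290) or without both libraries numbered 1 (camera adjusted p 0.0494).

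Of 19 fibroblast and dermal genes, 4 rose, 1 fell and 14 did not pass; adjusted over the list alone, 6 rose and 2 fell (camera adjusted p 0.132, and 0.441 with an estimated correlation). Fibronectin, Fn1, rose from 196 ± 26.2 to 496 ± 76.6 CPM and fibrillin, Fbn1, from 25.4 ± 5.61 to 71.2 ± 11.1 CPM. Col6a2 rose from 23.8 ± 4.03 to 48.1 ± 10.5 CPM, lost without control 3 or Eed cKO 3 (edgeR adjusted p up to 0.110), and Col6a1, chosen after its value was seen, from 35.9 to 61.1 CPM. Periostin, Postn, fell from 1645 ± 270 to 866 ± 57.7 CPM. The dermal collagens Col1a1, Col1a2 and Col3a1 had log2 fold changes of -0.15, 0.26 and -0.02.

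Of 18 immune and Langerhans cell genes 0 rose and 0 fell in edgeR, and adjusted over the list alone 0 rose and 2 fell, while all 18 had a negative log2 fold change (median -0.79). Lysozyme, Lyz2 (log2 fold change -1.70, edgeR adjusted p 0.0503), and the complement gene C1qc (log2 fold change -1.61, edgeR adjusted p 0.0702) came closest. Both were called without control 2 (edgeR adjusted p 0.00553 and 0.0479). At an unadjusted p under 0.05 there were 6 genes, while DESeq2 called 2 lower and limma-voom 0. The list moved down in camera (adjusted p 0.000244) but not with an estimated correlation (adjusted p 0.510) or in fry (adjusted p 0.358). The list's mean log2 CPM was 3.67 ± 0.770 in control and 2.55 ± 1.23 in Eed cKO (SD, n = 3 each; two-sided exact permutation p 0.3, where the smallest possible is 0.1).

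Of 18 immediate early genes, which dissociation of tissue can induce, 2 rose and 0 fell, with the same counts adjusted over the list alone (camera adjusted p 0.406, and 0.809 with an estimated correlation). The zinc-finger genes Egr3 and Egr2 rose from 23.6 ± 4.24 to 95.2 ± 11.3 CPM and from 8.16 ± 3.17 to 28.8 ± 7.41 CPM. Of 10 neuron and Schwann cell genes 1 rose, Rbfox3, and 0 fell, also adjusted over the list alone (camera adjusted p 0.126, and 0.325 with an estimated correlation). The Rbfox3 call was lost in each fit without 1 of the 6 libraries (edgeR adjusted p up to 0.170), with a log2 fold change of 4.61 that was 5.99 without control 2 and 3.91 without Eed cKO 1. The neuron list passed upward without Eed cKO 1 (camera adjusted p 0.0321). In edgeR 0 of 8 melanocyte genes (camera adjusted p 0.613, and 0.809 with an estimated correlation), 0 of 11 endothelial genes (0.547 and 0.893) and 0 of 10 muscle genes (0.295 and 0.441) were called, also adjusted over the list alone. At an unadjusted p under 0.05 there were 2 melanocyte, 0 endothelial and 1 muscle genes, and DESeq2 and limma-voom called 0 in each list. The endothelial list passed downward without control 2 (camera adjusted p 0.000295). In edgeR 0 of 2 erythroid and 0 of 2 sex-linked genes were called, also adjusted over the list alone, in DESeq2 and in limma-voom, and 0 had an unadjusted p under 0.05. Both lists were too short for a set test.

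**Figure D4:**
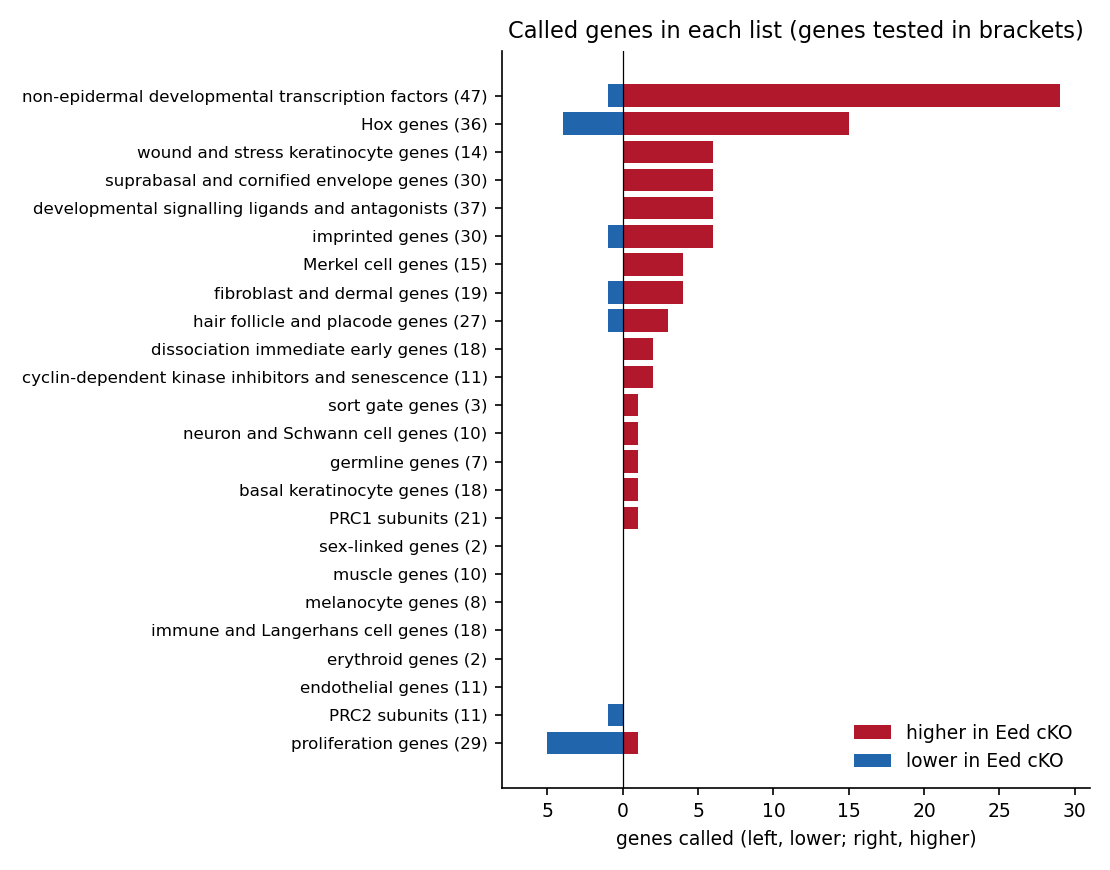
Number of genes called lower (blue, to the left) and higher (red, to the right) in Eed cKO in each of the 24 fixed lists, with the number tested in brackets. The developmental transcription factor list had the most calls, 29 higher and 1 lower.

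Of the 3 genes whose proteins define the sort, Epcam rose from 82.1 ± 20.4 to 140 ± 17.4 CPM (log2 fold change 0.77, edgeR adjusted p 0.0433), a call lost without control 1, control 3, Eed cKO 2 or Eed cKO 3 (edgeR adjusted p up to 0.171). Itga6 (log2 fold change 0.18) and Ly6a, which encodes Sca1 (log2 fold change 0.17), were not called; adjusted over the list alone, 1 rose and 0 fell. The sort gate list did not pass (camera adjusted p 0.208, and 0.441 with an estimated correlation). The ribosomal RNA precursor Rn45s took 3.79 ± 1.54% of control counts and 6.97 ± 0.258% of Eed cKO counts. Xist was at 8.55 CPM and the Y-linked Ddx3y at 121 CPM in Eed cKO 2, while the other 5 libraries had Xist between 5297 and 7757 CPM. By these genes Eed cKO 2 is male and the other 5 libraries, all controls among them, are female. The model held no term for sex.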

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

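Leaving out Rn45s and leaving out both libraries numbered 1 were chosen after the results were seen. No called gene changed sign in any setting, and higher genes stayed between 71.5% and 90.2% of the calls. Over the named genes, 1760 repeats kept direction and side of the threshold, 93 lost a call, 33 gained one and 19 changed sign. For the lists the numbers were 319, 13, 4 and 16.

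DESeq2 gave 811 higher and 273 lower genes, 659 at least doubled and 87 at least halved. Without a filter on low counts 257 were lower and 81 at least halved, with more genes tested. With the replicate block 269 were lower and 90 at least halved (675 were higher). The residual correlations of libraries with the same number were 0.23, 0.11 and -0.00, and 0.23 was the largest between any control and Eed cKO library. The libraries numbered 1 lay together on the second principal component of log2 CPM (20.6% of variance). Control 1 was at 46.8 and Eed cKO 1 at 47.4, with the other libraries between -44.3 and -5.01. What the libraries numbered 1 have in common was not tested. Without both libraries numbered 1, 71 were at least halved. With an estimated correlation 1 list passed. The cause was not tested for these counts. The estimate was below the preset of 0.01 for the signalling (0.0034), imprinted (-0.0013) and developmental transcription factor (-0.0080) lists. Their adjusted p nevertheless rose to 0.126, 0.161 and 0.00208 in camera, so a higher correlation does not account for that rise. The other lists that passed with the preset had estimates above it. Leaving out 1 library gave 302 to 456 higher, 35 to 118 lower, 289 to 413 doubled and 27 to 85 halved genes, with fewer samples, and 8 to 10 lists.

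All sign changes were in uncalled genes and lists, and the cause was not tested. Without both libraries numbered 1, log2 fold changes were 0.67 for Vwf, 0.19 for Alas2 and -0.32 for Ly6a. Krt5 had 0.0013 with RLE, 0.011 with upper-quartile scaling, 0.0017 with the 1 CPM filter, 0.00040 in DESeq2 and 0.0057 without Rn45s. Leaving out 1 library, the log2 fold changes ran from -0.17 to 0.028 for Ezh1, -0.14 to 1.82 for Tyr, -1.36 to 0.58 for Vwf and -0.31 to 0.090 for Alas2. They ran from -0.10 to 0.45 for Ly6a, -0.10 to 0.12 for Krt5 and -0.27 to 0.034 for Krt14.

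Camera adjusted p without both libraries numbered 1 was 0.735 for the hair follicle and for the kinase inhibitor lists, and 0.0494 for the germline list, which passed upward. With the 1 CPM filter it was 0.617 for kinase inhibitors and 0.499 for germline genes, which had 0.720 when thinned and 0.999 without Rn45s. Leaving out 1 library it ran from 0.453 to 0.977 for hair follicle, 0.694 to 0.977 for kinase inhibitors, 0.142 to 0.977 for immediate early, 0.0290 to 0.971 for germline, 0.309 to 0.975 for melanocyte and 0.000295 to 0.971 for endothelial genes. The wound list, called with all libraries, had 0.141 with the replicate block and 0.0557 without both libraries numbered 1. Atoh1 (40 Eed cKO counts) and Krt20 (24) fell below the filter on low counts and were not tested.

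Some genes not called in edgeR passed in other settings, and the cause was not tested. With the replicate block the edgeR adjusted p was 0.0123 for Ezh2, 0.00488 for Krt1, 0.0243 for Lor, 0.00825 for Wnt4, 0.0382 for Lyz2 and 0.000750 for C1qc. In DESeq2 the adjusted p was 0.0120 for Krt1, 0.0485 for Lor, 0.0170 for Wnt4, 0.00415 for Lyz2, 0.00723 for C1qc, 0.0388 for Krt18, 0.0418 for Cdkn1b and 0.0342 for Epop. Without a filter on low counts the edgeR adjusted p was 0.0133 for Ezh2, 0.0105 for Wnt4, 0.00279 for Krt1, 0.0398 for Lor, 0.00158 for Lyz2 and 0.000418 for C1qc. Wnt4 also passed in limma-voom (adjusted p 0.0382) and Lyz2 in edgeR with robust dispersion (adjusted p 0.0426). Without both libraries numbered 1 the edgeR adjusted p was 0.0428 for Ezh2, 0.0184 for Wnt4 and 0.0144 for Krt1. That setting also lost calls, with edgeR adjusted p 0.0728 for Cx3cr1, 0.0570 for Enkd1, 0.104 for F13a1, 0.0852 for Cysltr1, 0.0535 for Ncam1, 0.117 for Rab3b, 0.0715 for Sfn, 0.233 for Rbfox3 and 0.0583 for Epcam. In limma-voom the adjusted p was 0.0943 for Krt71, 0.220 for F13a1, 0.105 for Rab3b and 0.0837 for Rbfox3. With upper-quartile scaling the edgeR adjusted p was 0.0570 for Krt71, 0.0561 for Recql4 and 0.0559 for F13a1. Fitted log2 fold changes of genes with no control count were lower in limma-voom, at 10.24 for Sp8, 9.59 for Hoxa10, 9.22 for Sp9, 8.96 for Tbx5, 8.44 for Dmrt3, 7.28 for Isl1, 6.94 for Sox2 and 6.23 for Cdkn2a. Thinning gave 10.43 for Gata4 and 11.15 for Hoxc10.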

Other observations

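The tests of dermal fibroblasts and of shared reads and baseline level in the Hox genes were chosen after the results were seen. So were those of immune genes, of keratins and of p53 targets.

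Several large rises fell outside the naming rule and were chosen after their values were seen. Sfmbt2, which encodes a Polycomb-related protein and is imprinted in extraembryonic tissue, had the smallest edgeR adjusted p, 1.75e-09. It rose from 1.41 ± 0.170 to 118 ± 5.99 CPM. The imprinted gene Zdbf2 rose from 6.14 ± 0.756 to 65.5 ± 1.47 CPM. The zinc-finger gene Zfhx4 rose from 4.79 ± 2.64 to 142 ± 21.9 CPM, and Gas7 from 111 ± 15.2 to 419 ± 21.7 CPM. The epidermal connexin genes Gjb2 and Gjb6 rose from 21.1 ± 3.54 to 96.8 ± 12.6 CPM and from 7.43 ± 3.06 to 26.7 ± 1.98 CPM. The Hox noncoding RNA gene Hotair had 0 control and 93 Eed cKO counts. Lars2, among the most abundant called genes, rose from 1276 ± 571 to 3228 ± 65.5 CPM. The ribosomal RNA precursor Rn45s moved the same way, from 3.79 ± 1.54% to 6.97 ± 0.258% of counts, also with the wider spread in control. Whether ribosomal reads add to the Lars2 counts was not tested, so its rise is uncertain.

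Cell cycle transcription factor genes were among the falls, also chosen after their values were seen. E2f8 fell from 157 ± 5.14 to 83.4 ± 9.05 CPM, E2f7 from 111 ± 12.9 to 64.3 ± 6.97 CPM and Foxm1 from 175 ± 11.3 to 108 ± 4.96 CPM. The cyclin gene Ccnd2 rose, from 1125 ± 159 to 1930 ± 174 CPM. The Hedgehog effector Gli2 fell from 439 ± 38.3 to 229 ± 32.6 CPM and the ectodysplasin adaptor Edaradd from 270 ± 30.9 to 154 ± 19.3 CPM.

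More genes were higher than lower in Eed cKO. A gene near 0 in control can rise but hardly fall, and 141 higher but 0 lower genes had a control mean under 1 CPM. The part that this plays in the excess was not tested. The choice among scalings was not the whole cause, since higher genes made up at least 80.1% of the calls with RLE, upper-quartile or thinned scaling. These scalings gave close values, with a median log2 fold change over all genes of -0.003, 0.003 and -0.008, against -0.011 in the main fit. A scaling error common to all of them was not tested. Dermal fibroblasts in the Eed cKO sort were also excluded as the whole cause: Col1a1, Col1a2 and Col3a1 summed to 269 ± 12.3 CPM in control and 273 ± 28.4 CPM in Eed cKO, a ratio of 1.02 (0.867 to 1.14 over 9 library pairs). The fibroblast list mean was nevertheless higher in every Eed cKO library, at 5.10 ± 0.121 against 4.84 ± 0.155 log2 CPM, and Fn1, Fbn1, Col6a1 and Col6a2 rose. The cause of those rises was not tested. Loss of Polycomb repression may underlie the excess of rises, a hypothesis not tested here, which a map of the PRC2 histone mark in control cells would test.

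Hox changes rose with paralog group across the 36 tested genes (Spearman rho 0.84, Pearson r 0.83, permutation p 1e-05, the smallest that 100000 permutations give). Genes are not independent replicates. The trend held in the 20 genes sharing no exonic base with another gene (rho 0.88, permutation p 1e-05), so shared reads fail as the sole cause. The 4 falls were also called with RLE and upper-quartile scaling, so the choice among these scalings fails too. Both scalings moved the values little (Hoxa2 log2 fold change -1.585 and -1.577, against -1.594), and an error common to them was not tested. The call of 1 fall, Hoxa4, was lost without control 2, Eed cKO 2 or Eed cKO 3 (edgeR adjusted p 0.1001, 0.0830 and 0.0579). Among the 17 genes with at least 5 CPM in control rho was 0.65 (permutation p 0.0052). That set holds 0 genes of groups 9 to 13, whose control means reach at most 2.89 CPM. Draws of other genes with the same control means, tested or not, held a median of 0 and at most 3 higher genes, against 14 of 16 (p 1e-04). For Hox genes with no control count these draws take in rows with no count in any library and rows that the filter removed. Such rows cannot be called higher, which keeps the drawn counts low. Neighbours are not independent, so 1 gene per cluster was also considered. The highest matched shares of the 4 clusters multiply to 3.35e-07. That product is no bound on p, since any of several genes in a cluster could have been the one that rose. Draws among tested genes held a median of 7 and at most 12, against 14 of 14 (p 1e-04). Matched genes did not reach the Hox count in these draws, which take neighbouring genes as independent. Low baseline as the sole cause of the rise of groups 9 to 13 was therefore not excluded. Among tested genes with 1 per cluster p was 0.0681, the smallest that 4 clusters can give there, so that test is void: the filter keeps silent genes mainly where Eed cKO expresses them, and 52.99% of the matched genes rose. A part played by low baseline stays open.

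Immune and Langerhans cell genes lay lower in Eed cKO by 1.12 on the log2 scale in the list mean (cKO minus control -1.12, two-sided exact permutation p 0.3). The list holds genes of several immune cell types, so it does not isolate myeloid cells. The highest Eed cKO library lay 1.05 above the lowest control library, an overlap that carry-over varying between libraries could give. In libraries 1, 2 and 3 the list mean was 4.42, 2.88 and 3.72 in control and 3.93, 1.56 and 2.17 in Eed cKO. Within each number the Eed cKO library was thus lower, but the numbers are not stated to pair libraries. The permutation p takes no account of them. The sort took EpCAM-positive cells, and Langerhans cells also carry EpCAM. The 3 collagens did not fall with the list: their mean log2 fold change was 0.03, which is 0.82 above the list median. That comparison leaves out the spread of the list between libraries, an SD of 0.770 in control and 1.23 in Eed cKO. Of 11 endothelial genes 8 were negative and 3 positive (median log2 fold change -0.61). A loss of several non-epidermal types was therefore not excluded. A biological loss of immune cells was not tested.

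Loss of Eed could raise X-linked genes in female cells, and this was not seen in the 5 libraries with high Xist and next to no Y-linked counts. The median log2 fold change was 0.00 for 516 X-linked and -0.00 for 14526 autosomal genes, a difference of 0.00426 (permutation p 0.86). Of the X-linked genes 2.33% were higher, against 2.26% of autosomal genes.

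Genes that rose lay next to each other, in the order of tested genes on the chromosomes, more often than by chance. Genes not tested may lie between, and the pair Igfbp7 and Adgrl3 spans 77349240 to 81825133 on chromosome 5. The pairs Emx2os with Emx2 and Vax2os with Vax2 may share reads, since the strand setting is not known. Outside the Hox clusters 48 adjacent pairs both rose, against a median of 16 and a maximum of 32 over 10000 permutations within expression bins (p 1e-04, the smallest possible). Of these pairs 32 did not share a name stem. With 1 gene kept per run of a family there were 32 pairs, against a permuted maximum of 30. Examples that share a name stem are Tbx3 with Tbx5, Zic1 with Zic4 and Cdkn2a with Cdkn2b. Examples that do not are Mtap with Cdkn2a, Sp8 with Abcb5, and Abcb5 with Itgb8.

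Of 34 keratin genes tested 10 rose (29.4%, against 3.33% of other genes). The family was picked after some of the rises had been seen, so the Fisher exact p of 1.17e-07 is void as evidence. Krt7, a simple-epithelium keratin, rose from 3.15 ± 1.88 to 100.1 ± 21.4 CPM, and Krt79, of the follicle infundibulum, from 7.55 ± 1.74 to 55.7 ± 5.47 CPM.

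The rise of Cdkn2a raised the question whether p53 target genes rose. A list of 41 was written after some members had been seen among the rises, so its first test is void as evidence: 6 of 40 tested rose (15.0%, against 3.36% of other genes; Fisher exact p 0.00214). They were Phlda3, Ccng1, Zmat3, Plk2, Ddit4l and Sfn. Ckap2, which had been taken for a rise when the list was written, fell without being called (log2 fold change -0.41). With those 6 and Ckap2 taken out, the 33 left had a median log2 fold change of 0.27, against -0.02 for other uncalled genes (one-sided Wilcoxon p 0.000547, across genes that are not independent). With Ckap2 kept, the 34 had a median of 0.26 and a p of 0.00131. The classical targets Cdkn1a (log2 fold change 0.55, edgeR adjusted p 0.282) and Mdm2 (-0.08, edgeR adjusted p 0.902) were not called. A modest p53 response may be present, on a list not fixed in advance.

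The 6 libraries make 10 splits into 3 and 3, too few for a share under 0.05. The real split was the 1 of 10 with the largest value in each count. It gave 499 higher, 120 lower, 437 at least doubled and 42 at least halved genes, and the highest other split gave 1 in each, taking the larger of its directions since a split has none. For gene lists the real split passed 9 and the highest other 6. Every other split mixes the genotypes, which moves any genotype effect into the spread within its groups. Low gene counts in those splits are therefore no measure of chance.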
